A study of Homo sapiens with 24 samples.

How the data were processed

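RNA from 24 samples of 2 human colorectal adenocarcinoma cell lines, HT-29 and SW480, was analysed. Per the labels' protocols, single cells were sorted by forward scatter into plate wells and grown into clones, RNA was extracted with a column kit, and 100 ng of RNA was used per sample. Per the labels, SW480 cells and clones grew in RPMI-1640 and HT-29 cells and clones in McCoy's medium, so the medium and the line cannot be told apart. The labels placed 11 samples in the HT-29 clones, 11 in the SW480 clones, and 1 parental sample in each line. Each clone is a separate culture grown from a single cell, and nothing in the labels describes repeat cultures of a clone or of a parental population. The p-values therefore measure the spread between these clones, and the parental samples have no replicate. Clones are numbered in the order of deposition, and the numbers pair no samples.

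The deposited table held log2 values with 2 decimals for 784 probes, and the authors' instrument, counting software and normalization are not given in the sources used here. The probe names (6 positive and 8 negative controls beside 770 genes) are those of a digital barcode counting panel. Gene values under 5 were tested against whole-count steps: 100% of them lay within 0.011 log2 of log2 of a whole number plus 1 offset per sample, which ranged from -0.26 to 0.24. Values under 0 had been set to 0, and counts of 0 and 1 shared the lowest level. The control probes carried no offset. Counts were recovered from the deposited log2 values by removing the offset. They served for depth, background and counting noise, while all tests used the log2 values as deposited. The symbols of all 770 genes were matched to the GRCh38.p14 gene table, 754 by current symbol and 16 by an older one. That table gave gene names, chromosomes and the order of genes along a chromosome. No coordinates are printed, because the panel's build is not given in the sources used here.

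Recovered gene counts per sample ranged from 175511 to 321010. The background limit of a sample was the mean plus 2 SD of its 8 negative control counts. A gene was taken as above background in a line when at least 6 of its 11 clones exceeded that limit. This held for 488 genes in HT-29, 509 in SW480 and 443 in both, and 216 genes passed in neither line. The noise expected from counting was computed from these counts and covers counting error only. Where no clone of one line exceeded background, the fold is given as at least the ratio of the other line's mean to the dim line's mean floor (per sample, the higher of its limit and the measured value, as means of log2 values).

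Differences in expression were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean for each of the 4 groups and all 24 samples in the fit, so that the single parental samples are assumed to vary as the clones do. P-values were adjusted by Benjamini-Hochberg over 770 genes at a threshold of 0.05. The contrasts were HT-29 minus SW480 clones, clones minus parental in each line, the difference between these, and HT-29 minus SW480 parental. Of 28 gene lists fixed beforehand, 24 had at least 5 measured genes and were tested with limma's camera (inter-gene correlation 0.01, and again with an estimated correlation) and with fry. The fixed lists held 461 of the genes, 50 of them in more than 1 list. Lists with fewer genes are only counted. The 23 chromosomes with at least 5 genes formed their own family. A clone's distance was the root mean square log2 deviation from the mean of the other clones of its line, over the 443 genes above background in both lines. Line means of that distance were compared by a two-sided permutation test of 100000 resamples. Spread per gene was compared by the absolute deviations from the line's median, with the same number of resamples and Benjamini-Hochberg adjustment. The gene filter of this last test had not been fixed in advance. The same 443 genes were chosen before its result was seen, and all 770 genes served as an alternative. The parental distance was ranked among the clones' distances with a rank p, one-sided for a parental sample farther out, whose smallest possible value is 0.0833. The parental sample was set against the mean of all clones of its line and each clone against the mean of the others, so the ranks are not strictly exchangeable. Co-variation was the mean Pearson correlation over clones of gene pairs on the same chromosome minus that of other pairs, tested one-sided with 10000 permutations of chromosome labels. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

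Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest called differences in each direction between lines, up to 3 called members of each list, genes fixed by name (among them BRAF, APC, SMAD4, MYC, CTNNB1 and PIK3CA), and up to 8 called genes per direction against the parental sample. For heterogeneity it took the 8 genes with the largest SD in each line and up to 8 per direction of the spread test with the largest difference, and for chromosomes up to 3 genes on each one past the threshold. Some genes it takes, and the result of 1 list, are not reported here. Genes named outside it were chosen after their values were seen, and the text says so. The alternatives fixed in advance were median centring, quantile normalization, centring on the reference genes, a filter at the 25th percentile of gene means, leaving out the 2 clones with a different name prefix, limma-trend with robust variances, a required absolute log2 difference of 1, other samples in the fit, other distance and spread measures, and leaving out each clone. Alternatives that need linear values or raw counts were not run. Positive control scaling, genes above background, values raised to the highest background limit, values raised to each sample's own limit, and all 770 genes were added after the data had been seen.

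On simulated data of the same size, the comparison of lines recovered 20% of 50 genes changed 1.414-fold, 70% changed 2-fold, 98% changed 4-fold and 100% changed 8-fold, with 6 of 570 unchanged genes called. Against 1 parental sample the recovered shares were 10% at 2-fold, 52% at 4-fold and 80% at 8-fold. The spread test, simulated over 443 genes, recovered 12% of 50 genes at an SD ratio of 2, 28% at 3, 78% at 5 and 92% at 8, and called 0 of 243 unchanged genes. A list shifted by 1 log2 unit was called, and 0 of the other simulated lists were. The simulated genes varied independently, while measured lists were correlated (estimated at 0.258 for cell cycle genes). The lack of false list calls therefore does not carry over to the measured data.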

Results

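Expression of 770 cancer pathway genes was measured in 24 samples of HT-29 and SW480, colorectal adenocarcinoma cell lines. The series compared clones grown from single cells of each line with respect to clonal evolution and heterogeneity, and its title concerns genomic imbalances. There were 11 HT-29 clones, 11 SW480 clones and 1 parental sample of each line. Recovered gene counts were 226026 to 305090 in HT-29 clones, 175511 to 247336 in SW480 clones, 321010 in the HT-29 parental sample and 179445 in the SW480 parental sample. Between 465 and 559 genes per sample lay above background. Profiles of HT-29 clones correlated with each other at 0.933 to 0.973 across genes, and those of SW480 clones at 0.838 to 0.966. Genes are not independent replicates, and these correlations describe pairs of samples. Between the lines they were 0.718 to 0.807. No pair of clones within a line agreed within counting noise (chi-square per degree of freedom of at least 13.7), so none was treated as 1 library deposited more than once. This covers counting error only and not the variation between cultures of 1 clone.

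The first comparison set the 11 HT-29 clones against the 11 SW480 clones. MMP7, which encodes the matrix protease matrilysin, stood at a log2 value of 11.75 ± 0.92 (SD, n = 11) in HT-29 and 2.69 ± 0.61 in SW480, where 1 of 11 clones exceeded background. NGFR, a neurotrophin receptor, was at least 348-fold higher in SW480 (11.35 ± 0.86), with no HT-29 clone above background. The growth factor FGF3 was at least 116-fold higher in SW480, at 9.77 ± 0.89. BMP7, a bone morphogenetic protein, reached 10.23 ± 0.55 in SW480 against 2.30 ± 1.35 in HT-29, where 2 of 11 clones exceeded background. The hepatocyte growth factor receptor MET was higher in HT-29, at 10.59 ± 0.42 against 5.73 ± 0.82.

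Among the other genes with the largest log2 differences, HT-29 clones had more CREB3L1 (6.34), DTX4 (6.06), SGK2 (5.61), the death ligand TNFSF10 (4.56), NFKBIZ (4.37) and the nuclear receptor PPARG (4.30). PLA2G4A was at least 16.2-fold higher in HT-29, PROM1 at least 24.4-fold, CBLC at least 9.41-fold and MECOM at least 8.41-fold. SW480 clones had at least 44.3-fold more INHBB, which encodes an activin subunit, 20.6-fold more FGFR1, 16.6-fold more WNT5A and 12.8-fold more GZMB. The log2 differences, HT-29 minus SW480, were -7.28 for IGFBP3, -7.14 for BAMBI, -6.15 for NKD1 and -6.01 for the D-type cyclin CCND2. All of these genes passed limma's adjusted threshold, with the highest adjusted p at 2.22e-05 for CCND2. In the lower line, DTX4, SGK2, IGFBP3 and BAMBI exceeded background in 1 of 11 clones and CCND2 in 2 of 11, so their differences are against a mean near background and depend on it. The clones of the lines overlapped for TNFSF10 and CCND2.

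**Figure D1:**
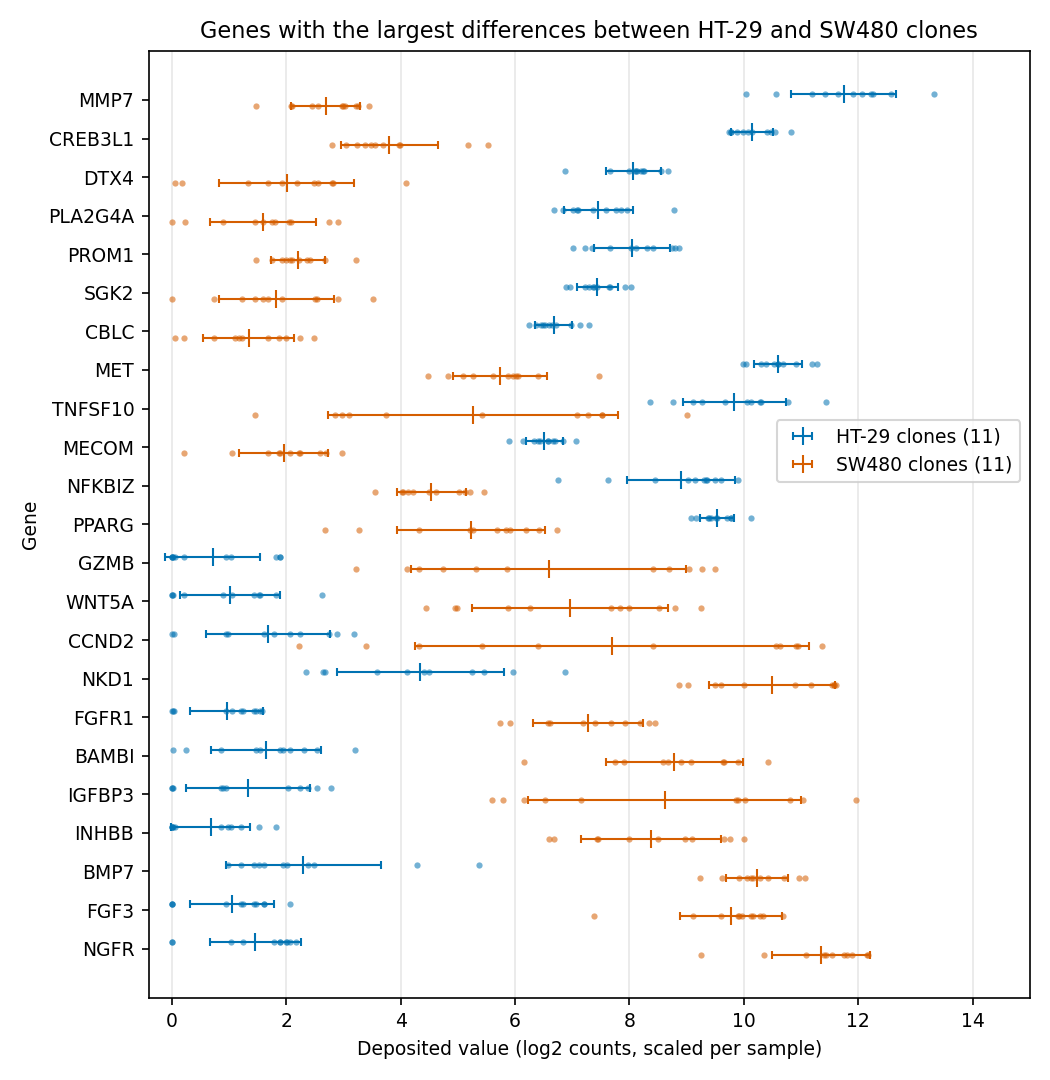
Deposited log2 values (horizontal axis, log2 counts scaled per sample) of 23 genes with the largest called differences between lines, with genes on the vertical axis. Points are 11 HT-29 clones and 11 SW480 clones, and bars give mean and SD. MMP7 stood at 11.75 in HT-29 against 2.69 in SW480, and NGFR at 1.46 against 11.35.

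In the lists of secreted ligands and of several developmental pathways, more of the called genes were higher in SW480, while no list passed camera between lines. Many of these genes were dim, and among genes above background in neither line all 69 that passed were higher in SW480. Of 41 growth factor ligands, 7 were higher in HT-29, 17 were higher in SW480 and 17 did not pass. FGF13 was at least 5.22-fold higher in SW480. Of 29 Wnt ligands, receptors and signalling genes, 8 were higher in HT-29 and 14 in SW480, with WNT5B at least 6.69-fold higher in SW480. Among 14 Wnt target genes, 4 were higher in HT-29 and 6 in SW480. LEF1, a transcription factor of the Wnt pathway, differed by -5.67, with 1 of 11 HT-29 clones above background. Of 17 Notch genes, 3 were higher in HT-29 and 7 in SW480, and the ligand gene DLL3 differed by -4.46, with 1 of 11 HT-29 clones above background. None of 6 Hedgehog genes was higher in HT-29, and 4 were higher in SW480, among them GLI3 (-5.69, above background in 1 of 11 HT-29 clones), SMO (-2.36, in 2 of 11) and the receptor gene PTCH1 (-1.28). Of 13 mesenchymal genes, 1 was higher in HT-29 and 7 in SW480, with fibronectin (FN1) at least 5.20-fold higher. Only 4 of these 13 and 21 of the 41 ligands exceeded background in a line. Negative control counts were also higher in SW480 clones, at 5.86 ± 1.26 against 3.68 ± 0.79 (difference 2.18, permutation test, p = 3.0e-05). So were positive controls, at a mean log2 count of 9.22 ± 0.18 against 8.89 ± 0.20 (permutation test, p = 0.00074). Total gene counts were lower in SW480 clones, at 17.69 ± 0.18 log2 against 17.97 ± 0.15 (permutation test, p = 0.00107). A difference in the assay between the lines' samples was not tested and cannot be told apart from the line. The majority of calls in each of these 6 lists lay on the SW480 side under all 4 other scalings, and was narrowest for the ligands after quantile normalization (9 against 10) and for the Notch genes with positive control scaling (5 against 6).

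In the lists of colorectal cancer drivers, PI3K and AKT signalling, apoptosis and epithelial differentiation, more of the called genes were higher in HT-29, again with no list past camera. Of 24 colorectal cancer driver genes, 12 were higher in HT-29 and 3 in SW480, and the receptor gene ERBB2 differed by 2.86 and TGFBR2 by 2.48. Of 21 PI3K and AKT genes, 12 were higher in HT-29 and 2 in SW480, with the insulin receptor substrate IRS1 at 3.26. PIK3CD was on the other side, at -3.31, with 1 of 11 HT-29 clones and 7 of 11 SW480 clones above background. Of 20 apoptosis regulators, 10 were higher in HT-29 and 2 in SW480, with BIRC7 at 2.90 and FASLG at -2.24, each above background in 2 of 11 clones of the lower line. All 3 measured genes of intestinal epithelial differentiation were higher in HT-29, among them E-cadherin (CDH1, 3.60) and KLF4 (1.26). Of 3 cancer stem cell markers, 2 were higher in HT-29, and of 2 hypoxia and glycolysis genes, VEGFA was (2.97). The majority of calls in each of these lists lay on the HT-29 side under all 4 other scalings, while the median of the apoptosis list turned to -0.10 after centring on reference genes.

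For most of the remaining lists the balance of calls was even, or was lost or turned under another scaling. Of 41 RAS, RAF and MAP kinase genes, 18 were higher in HT-29 and 12 in SW480, with MAP3K5 at 2.81, which turned to 13 and 14 after quantile normalization and 9 and 18 after reference gene centring. Chromatin regulators gave 16 and 8 of 39, with HDAC1 at 2.04, and turned to 6 and 15 after reference gene centring, with 9 each after quantile normalization. DNA repair genes gave 13 and 9 of 40, with MGMT at 2.13, and turned to 8 and 21 after reference gene centring, with 12 and 13 after median centring and 13 each after quantile normalization. Cell cycle genes gave 5 and 9 of 28, with CDC25B at -2.30 and CCND1 at -2.25, and turned to 8 and 6 with positive control scaling. TGF-beta and BMP genes were even, at 8 and 8 of 28, and ID1 was higher in HT-29 (3.78). Receptor tyrosine kinases were even as well, at 7 and 7 of 19, with NTRK2 at least 4.08-fold higher in SW480, and mitosis genes stood at 3 and 3 of 8, with RAD21 at 2.31. Inflammatory genes gave 6 and 4 of 17, with NFKBIA at 1.71, and 6 each after reference gene centring. MAPK feedback genes gave 4 and 5 of 17, with SPRY1 at 3.07 (3 of 11 SW480 clones above background) and ETV1 at -3.10, and 5 and 4 with positive control scaling. JAK-STAT genes gave 5 and 3 of 12, with SOCS2 at -2.79, and turned to 5 and 6 after median centring and 4 and 6 after reference gene centring. CDK inhibitors gave 2 and 1 of 7, with CDKN2A at 1.63, and 1 each under median centring, quantile normalization and reference gene centring. Of 40 reference genes, 19 were higher in HT-29 and 2 in SW480, with B2M at 3.18, and centring on these genes turned their own counts to 9 and 13. Of 9 immune cell markers, 1 was higher in HT-29 (CD14, at least 3.75-fold) and 5 in SW480, with 1 each after quantile normalization, and 2 of the 9 exceeded background in a line. Of 5 endothelial and stromal markers, 0 were higher in HT-29 and 2 in SW480, COL1A1 and PDGFRB, and 0 of the 5 exceeded background in a line. This last majority held under all 4 scalings.

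Among the genes fixed by name, CTNNB1, which encodes beta-catenin, was higher in SW480, at 13.22 ± 0.58 against 10.95 ± 0.14. SMAD4, a mediator of TGF-beta signalling, was higher in HT-29, at 6.20 ± 0.21 against 4.14 ± 0.73. BRAF (0.64, adjusted p = 0.00148) and APC (0.63, adjusted p = 0.00340) were higher in HT-29 and lost their calls after centring on reference genes, with BRAF also not called after quantile normalization. MYC (-0.45, adjusted p = 0.0768) did not pass, though it was called higher in SW480 after quantile normalization or reference gene centring, and also without HT-29 clone 2 or 3 or SW480 clone 4. PIK3CA (0.30, adjusted p = 0.420) did not pass.

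Between the clones of the lines, 452 of 770 genes passed, 237 higher in HT-29 and 215 in SW480, and 315 of them differed by at least 2-fold. For 151 genes the ranges of the lines did not overlap, 100 with HT-29 and 51 with SW480 above, where chance gives 0.000284% of genes. Among 443 genes above background in both lines, 278 passed (198 higher in HT-29). Among 111 above background in 1 line, 105 passed (66 higher in SW480), and all 69 that passed among 216 above it in neither line were higher in SW480. The split depended on scaling: centring on reference genes gave 154 against 373, with a median difference of all genes of -0.61 in place of -0.16, and positive control scaling gave 296 against 149 (0.19). The median difference was -0.28 after median centring and 0.06 after quantile normalization.

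None of 24 lists passed limma's camera test between lines, where 7 had an unadjusted p under the threshold. The lowest adjusted p was 0.0863, for the reference genes, and it was 0.506 with an estimated correlation. Fry, which tests whether the genes of a list move one way and not whether they exceed other genes, passed 19 of the 24. The median and the test differed in sign for CDK inhibitors, mitosis genes and receptor tyrosine kinases. Adjusted over the list alone, the calls higher in HT-29 and in SW480 were 13 and 3 for the driver genes, 7 and 18 for growth factors, 4 and 3 for mitosis genes and 4 and 7 for Wnt targets, and did not change in the other 20 lists. By chromosome, 0 of 23 sets passed camera, and 1 had an unadjusted p under the threshold, chromosome 13 with 0.0197 (adjusted p = 0.453), with 9 of its 13 genes higher in SW480 and 1 in HT-29.

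The next comparisons set the clones of each line against its parental population. In HT-29, 9 genes passed, and in each all 11 clones lay on the same side of the parental sample. Each clone alone against the others of its line gave 20 genes for HT-29 clone 9, 9 for SW480 clone 11, 1 for SW480 clone 6 and 0 for the rest, so a count of 9 is within what a single clone reached. Higher in the clones were the stem cell marker PROM1 (8.05 ± 0.66 against 5.49), the laminin gene LAMA5 (7.72 ± 0.50 against 5.60), PIK3R2 (6.86 ± 0.39 against 4.96), HDAC10 (5.86 ± 0.36 against 4.02), and the DNA repair genes NTHL1 (7.19 ± 0.27 against 5.57) and FANCC (5.99 ± 0.18 against 4.73). Lower in the clones were the interleukin receptor gene IL6R (3.31 ± 0.72 against 6.62), the cell cycle inhibitor CDKN2A (6.70 ± 0.17 against 8.49) and PPP2CB (9.16 ± 0.20 against 10.60). The log2 differences ran from -3.31 for IL6R to 2.56 for PROM1, with adjusted p between 0.0129 and 0.0449 in limma. At an unadjusted p under the threshold there were 107 genes. FANCC lost its call without HT-29 clone 4, 6, 7, 8, 9, 10 or 11 or SW480 clone 4, 7 or 9, and CDKN2A without HT-29 clone 7. Quantile normalization left 0 calls, median centring gave 6, all lower in the clones, and positive control scaling gave 28 higher and 1 lower. Other settings gave up to 37.

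In SW480, 0 genes passed in limma, and 37 had an unadjusted p under the threshold. The gene nearest to it, chosen after its values were seen, was the Hedgehog receptor gene PTCH1, at 6.50 ± 0.54 in the clones and 4.20 in the parental sample (difference 2.30, adjusted p = 0.0687, higher in 11 of 11 clones). It passed without HT-29 clone 1 or SW480 clone 2, 6 or 7, and under 5 of the alternative settings. The difference between lines in the step from parental to clones passed for 0 genes, with 65 at an unadjusted p under the threshold, so that a difference between HT-29 and SW480 in this step was not shown. Of the 24 lists, 0 passed camera in either line. An unadjusted p under the threshold was found for 3 lists in HT-29 and 7 in SW480, and the lowest adjusted p was 0.317 and 0.161. Fry passed 1 list in HT-29, the CDK inhibitors, lower in the clones (adjusted p = 0.00921), and 0 in SW480. The CDK inhibitors also passed fry, but not camera, for the difference between lines in the step from parental to clones. Their mean log2 step was -0.911 in HT-29 and 0.348 in SW480. Fry does not set a list against other genes, and the median of all genes for this difference was itself -0.354. It was not run on this difference under other scalings. Resting on 7 genes and 1 parental sample per line, it does not show that the step differs between lines. With 1 parental sample, a simulated 2-fold change was recovered for 10% of genes and a 4-fold change for 52%.

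The parental samples repeated much of the difference between lines. MMP7 stood at 12.18 in HT-29 and 3.12 in SW480, CDH1 at 11.77 and 6.60, FGF3 at 1.21 and 9.13, and NGFR at 2.79 and 9.47. In limma, 95 genes passed, 71 higher in HT-29 and 24 in SW480. Of these, 92 also passed between clones, all 92 with the same sign. Across genes, the differences between parental samples and between clones correlated at 0.820, and 388 of the 452 genes called between clones (85.8%) had the same sign. This test rests on 1 sample per line with the spread taken from the clones. The split turned to 27 against 47 after centring on reference genes, and was 35 against 22 after quantile normalization and 43 against 26 with positive control scaling. The reference genes passed camera (adjusted p = 0.0159, higher in HT-29), and did not with an estimated correlation (adjusted p = 0.449).

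Heterogeneity between clones was larger in SW480. An SW480 clone differed from the mean of the others by 0.834 ± 0.053 log2 (SD, n = 11) and an HT-29 clone by 0.593 ± 0.139 (n = 11), over 443 genes above background in both lines. The difference was 0.241 (two-sided permutation test, p = 0.00011). The 11 distances of a line share the same clones, while the test treats them as independent. Its p may therefore overstate the evidence. Counting noise alone would give 0.210 in SW480 and 0.191 in HT-29. HT-29 clone 9 lay at 0.973, and the other HT-29 clones at 0.469 to 0.631. Over the genes above background in SW480, the first principal component took 64.9% of the variance between its clones and parted 5 clones from 6. In HT-29 it took 34.8%, and its largest gap parted 1 clone from 10. Much of the SW480 spread thus lay along 1 split of the clones. The difference in distance was not tested with this component removed.

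**Figure D2:**
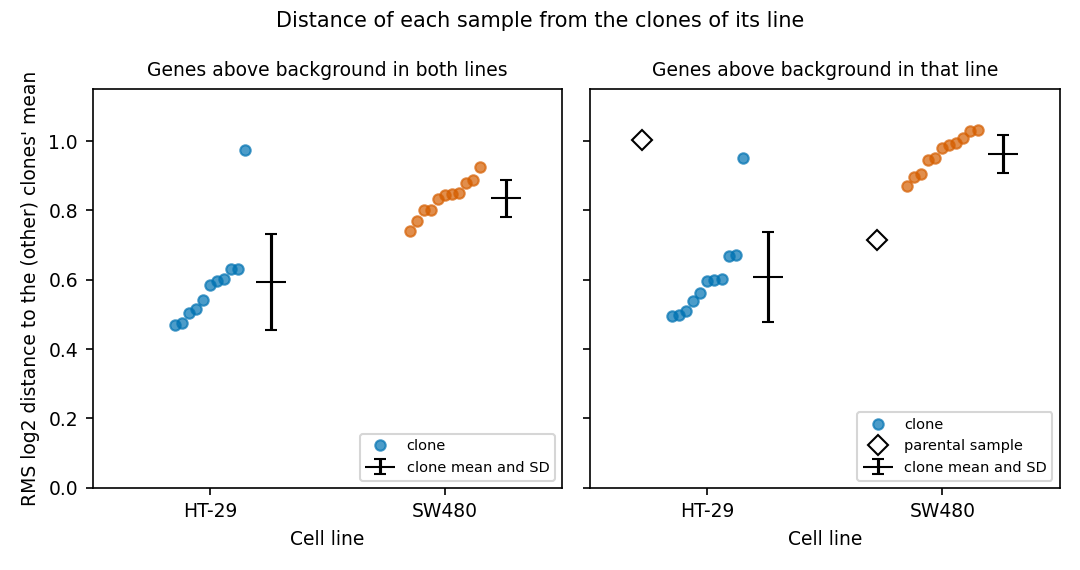
Root mean square log2 distance of each clone from the mean of the other clones of its line (vertical axis, log2 units), by line (horizontal axis), over genes above background in both lines (left) or in that line (right), with points for clones, bars for mean and SD, and diamonds for the parental samples. On the left, SW480 clones averaged 0.834 and HT-29 clones 0.593, with HT-29 clone 9 at 0.973, and on the right the parental samples lay at 0.715 and 1.00.

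The 8 genes with the largest SD between SW480 clones came from several lists. DKK4, which encodes a secreted Wnt antagonist, ranged from 0.90 to 14.47 (SD 5.25, n = 11), CCND2 from 2.22 to 11.37 (SD 3.44), the Notch effector HES5 from 2.48 to 11.06 (SD 3.09) and KITLG, the ligand of KIT, from 2.51 to 10.54 (SD 3.03). EGFR ranged from 2.74 to 9.35 (SD 2.69), FZD10 from 0.93 to 8.06 (SD 2.62), TNFSF10 from 1.45 to 9.01 (SD 2.53) and MAP2K6 from 0.00 to 7.36 (SD 2.52). For all 8 genes the lowest value lay under its clone's background limit (2.52 to 3.57 in clones 4, 5, 6 and 8). Their ranges and SDs therefore depend partly on background. In HT-29 the 8 genes were CCNA2 (SD 2.08), CDC25C (1.84), PTTG2 (1.59), the histone genes HIST1H3G (1.59) and HIST1H3B (1.54), and CCNB1 (1.53), each lowest in clone 9, and WNT11 (1.52) and NKD1 (1.46), each lowest in clone 1. The lowest values of CCNA2, CDC25C and NKD1 lay under the background limit (3.17 in clones 1 and 9).

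**Figure D3:**
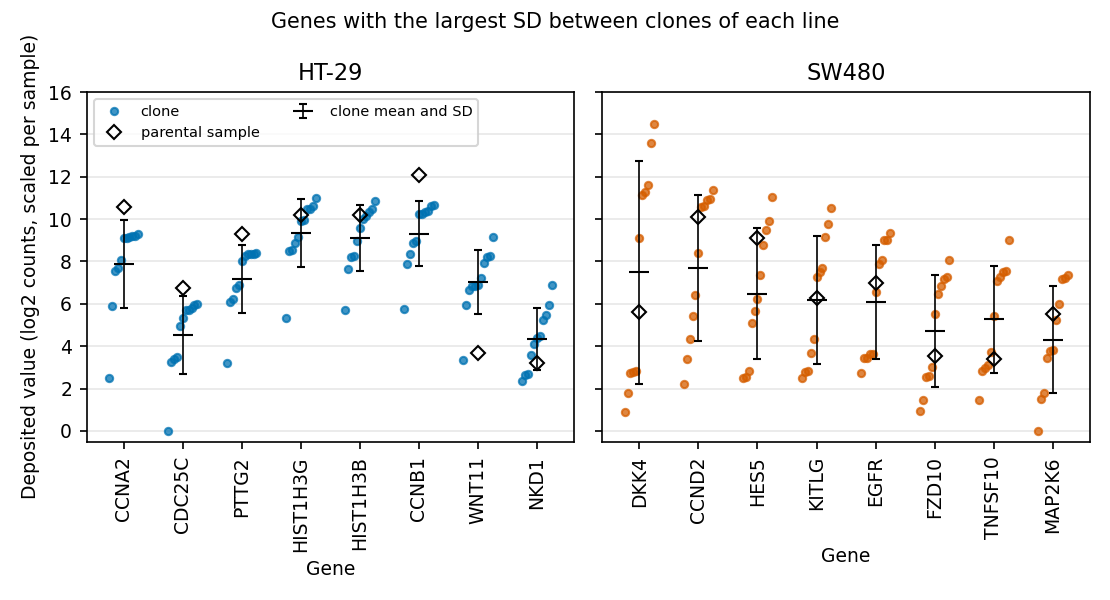
Deposited log2 values (vertical axis, log2 counts scaled per sample) of the 8 genes with the largest SD between clones of each line (horizontal axis), with HT-29 and SW480 in separate panels. Points are clones in order of value, bars the clone mean and SD, and diamonds the parental sample. DKK4 ranged from 0.90 to 14.47 in SW480 clones, and CCNA2 from 2.48 to 9.29 in HT-29 clones. Both lowest values lay under the background limit of their clone.

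Gene by gene, the spread differed between lines for 23 of 443 genes, all 23 with the larger spread in SW480. With squared deviations 132 genes passed, 20 of them with the larger spread in HT-29, and without the clones of the other name prefix 73 passed, 6 of them larger in HT-29. Quantile normalization gave 44 and reference gene centring 39, with 1 larger in HT-29 in each, while median centring and all 770 genes gave 12 each and values raised to each sample's limit gave 9. The largest differences in mean absolute deviation were those of KITLG (2.04), the Wnt receptor gene FZD7 (1.91), EGFR (1.89), the Notch modifier LFNG (1.54), TNFSF10 (1.51), BMP2 (1.45), the DNA demethylation enzyme TET2 (1.37) and CACNG6 (1.30). EGFR had an SD of 2.69 in SW480 and 0.66 in HT-29 (permutation test, adjusted p = 0.0188). The median SD over genes was 0.547 in SW480 and 0.367 in HT-29, and 306 genes (69.1%) had the larger SD in SW480. Median SDs of the lists were 1.05 and 0.448 for 8 Notch genes and 0.924 and 0.538 for 9 growth factor ligands in SW480 and HT-29. They were 0.676 and 0.678 for 26 cell cycle genes, and 0.535 and 0.590 for 10 JAK-STAT and interferon genes, where HT-29 had the larger one. The spread of lists was not tested. The number of called genes moved by over 1.5 times when single clones were left out, from 4 without HT-29 clone 8 or 10 to 75 without SW480 clone 6. All SW480 clones whose removal moved it that far lay on the larger side of a split of these clones, given under the other observations.

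The parental samples stood differently among their clones. The HT-29 parental sample lay 1.00 log2 from the mean of its clones, farther than any clone from the others (0.496 to 0.950, one-sided rank test, p = 0.0833, the smallest possible here). The SW480 parental sample lay at 0.715, closer than every clone (0.872 to 1.03, one-sided rank test, p = 1). The test asked only whether a parental sample lay farther out, so the SW480 p does not address its lying closer. The design can make no call at the threshold, and the difference between lines was not tested.

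Pooled over all chromosomes, gene pairs on the same chromosome correlated more between clones than other pairs in both lines. Single chromosomes differed widely. Among those tested, means ran from 0.0015 (chromosome 8) to 0.415 (chromosome 3) in SW480. In HT-29 they ran from -0.0267 (chromosome 4) to 0.221 (chromosome 15). The pooled values were not tested without the highest chromosomes. In SW480, pairs on the same chromosome correlated at a mean of 0.118 and other pairs at 0.0499 (difference 0.0680, permutation test, p = 0.0001, the smallest the permutations can give). In HT-29 the means were 0.0781 and 0.0610 (difference 0.0171, permutation test, p = 0.0045). Of 22 chromosomes tested in SW480, chromosome 3 passed, with a mean correlation of 0.415 over pairs of its 39 genes (adjusted p = 0.0022). Its mean fell to between 0.234 and 0.367 under 4 other scalings and to 0.178 without the first component, and it passed in each, but so did other chromosomes: 5 passed in all after reference gene centring, 3 without the first component and 2 under each of the other 3 scalings. Of 21 tested in HT-29, chromosome 7 passed, at 0.218 over 26 genes (adjusted p = 0.0315). The difference between lines was not tested.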

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

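The tests of higher background counts and of scaling, and the counts of other splits, were chosen after their results had been seen. The count of calls after subtraction of negative control counts was fixed before its result, and the sizes of the differences before and after were added later.

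The negative control probes, which match no human gene, were not tested as genes but set each sample's background limit. They carried more counts than the 3 that a count of 0 allows. Their mean was 5.864 counts in SW480 clones and 3.682 in HT-29 clones, and 6.75 in the SW480 and 4.125 in the HT-29 parental sample.

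Genes above background in neither line had a median difference between HT-29 and SW480 of -0.62, with quartiles of -0.90 and -0.29, and all 69 of them that passed were higher in SW480. Scaling stays open, since the median of these genes ran from -1.07 to -0.27 under 3 other scalings and was 0.09 after quantile normalization, and genes above background in both lines, with a median of 0.316, went both ways and had a median of -0.14 after centring on reference genes. Higher background in the SW480 samples may account for the shift of the set, since the negative controls differed by -0.70 on the same scale and subtraction of each sample's mean negative control count moved the median difference, SW480 minus HT-29, of all 216 genes from 1.48 to -0.768 scaled counts. Low expression of the 69 called genes in SW480 cells stays open: 6 of 69 were still called after subtraction in a permutation test per gene, against 41 before, but their median difference fell from 3.69 (quartiles 2.22 and 6.70) only to 1.44 (quartiles -0.029 and 4.45), at a median SD between clones of 3.06 before and 3.27 after. Fewer than 10% of calls left had been set beforehand as the value that excludes expression, and 8.70% were left. A lost call does not show that a difference is absent. The difference that stayed cannot decide either, because the 69 genes were picked as higher in SW480 in the same values. Of all 216 genes, 72 were higher in SW480 after subtraction.

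Between HT-29 and SW480 clones, 1 of 100 splits of the 22 clones, the real one, gave 452 genes, and the highest of the others gave 57. The other splits mixed both lines, so the line difference entered the spread within their groups and kept their counts low. With 100 splits no share under 1 of 100 can be reached, so this count alone does not exclude chance. For genes whose spread differed, 1 of 100 splits, again the real one, gave 23, and the highest other gave 1. These splits relabel the same deviations as the test per gene, so they add no separate evidence against chance. Leaving out 1 clone gave 4 to 75 such genes. For the fixed lists and for the chromosomes the real split gave 0, which any split reaches (100 of 100 in each), so these counts say nothing about chance. The highest of the others were 6 lists and 2 chromosomes.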

How the results depend on the processing

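Positive control scaling, both ways of raising values to background limits, the restriction to genes above background and all 770 genes were chosen after seeing the data. No paired analysis was possible because clone numbers follow the order of deposition only. Raw-count tests and a linear pseudocount were not run, since the values are log2. Except where a construction is named, the cause was not tested.

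Between HT-29 and SW480 clones, 315 to 602 genes passed under 14 alternatives, and 441 to 459 without 1 clone. The 602 came from raising values to each sample's own limit, which builds the background difference of the lines into dim genes. Against the parental sample, the 9 genes in HT-29 became 0 under quantile normalization, 14 after reference gene centring, 22 above the 25th percentile and 26 above background (fewer genes tested in both), 14 without the clones of the other prefix, 15 with limma-trend, 29 with positive control scaling, 37 with values raised to the highest limit and 19 with values raised to each sample's limit. Without 1 clone there were 7 to 12. In SW480 the 0 became 1 above the 25th percentile, 1 above background, 2 without the other prefix, 6 at the highest limit and 1 at each sample's limit, and 0 to 2 without 1 clone. The difference between these steps rose from 0 genes to 1 with positive control scaling and 15 at the highest limit, and stayed at 0 without any 1 clone. Raising values to 1 limit removes the spread of genes at it, so that BCL2 passed in SW480 at -0.16. The parental samples differed by 57 genes under quantile normalization, and by 89 to 103 without 1 clone.

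The larger distance between SW480 clones kept its direction and call in all 12 alternatives (permutation test, highest p = 0.00046), and was 0.224 to 0.284 without 1 clone. The distances of a line depend on each other in all of these settings too. The parental distance was 0.988 to 1.03 in HT-29 and 0.689 to 0.752 in SW480 without 1 clone. Co-variation within chromosomes, pooled over all of them, kept its call in both lines under 11 alternatives. The 25th percentile and background filters removed almost none of the genes in these tests. The 23 genes of the spread test became 12 after median centring, 44 under quantile normalization, 39 after reference gene centring, 73 without the other prefix, 9 at each sample's limit, 12 over all 770 genes and 132 with squared deviations (20 of them larger in HT-29). Leaving out 1 clone gave 4 to 75: 8, 9, 5, 8, 6, 13, 4, 4 and 13 without HT-29 clones 2, 3, 4, 5, 6, 7, 8, 10 and 11, and 65, 72, 75, 70, 71 and 73 without SW480 clones 1, 4, 6, 9, 10 and 11. These SW480 clones are those with first component scores above 0, the larger side of the split given below. Leaving 1 of them out makes both sides equal in number. For genes that follow the split, the line's median then falls between the sides, and deviations are taken from that median. The setting without the other prefix also leaves out SW480 clone 6.

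The list count of 0 became 1 between lines with positive control scaling (reference genes, adjusted p = 0.00668, and 0.517 with an estimated correlation) and 1 at each sample's limit (adjusted p = 0.0266, and 0.797 estimated), and 1 against the parental sample at each sample's limit (DNA repair in HT-29, adjusted p = 0.0187, and 0.942 estimated). Chromosomes stayed at 0. Of values for named genes between lines, 1072 kept direction and side of the threshold, 19 fell under it, 2 rose past it and 3 turned: CDKN1B to -0.0766 (reference gene centring), and PIK3CA to -0.061 and -0.15 (quantile normalization and reference gene centring). Low signal limits the 216 genes above background in neither line.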

Other observations

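All tests in this part were chosen after seeing the data, except the mixture of clone profiles and the gene pairs across both parts of the chromosome 3 gene order, which were fixed before their results.

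Each clone in turn was set against the other clones of its line in limma, so that the single clone has no replicate, the spread comes from the other clones of both lines, and the clone is assumed to vary as they do. For HT-29 clone 9, which also had the largest distance in its line, 20 genes passed, all lower in clone 9. Among them were the cyclins CCNA2, which was 5.95 log2 lower, and CCNB1 (3.91), the phosphatase gene CDC25C (4.96), the checkpoint kinase gene CHEK1 and the histone genes HIST1H3B and HIST1H3G. Over 26 genes of the cell cycle list, clone 9 lay at a mean log2 deviation of -1.56 from the median of the HT-29 clones per gene, clone 10 at -0.93 and the other HT-29 clones between -0.51 and 0.44. The median deviations of clones 9 and 10 were closer, at -1.085 and -0.99, with 20 of the 26 genes lower in clone 9 and 24 in clone 10. For SW480 clone 11, 9 genes passed. Lower there were the laminin genes LAMA3 (5.31) and LAMB3 (2.55) and the integrin gene ITGB6 (2.80), and higher were PDGFRB (-4.11, others minus clone 11), TNC (-3.84) and the collagen gene COL2A1 (-2.54). Of the other clones, SW480 clone 6 had 1 gene past the threshold, IL15, which was 2.96 lower there, and the rest had none.

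In SW480, DKK4 stood at 2.80, 11.29, 13.60, 0.90, 11.62, 2.74, 11.12, 9.12, 2.81, 1.81 and 14.47 in clones 1 to 11, and at 5.60 in the parental sample. EGFR stood at 9.01, 3.63, 3.64, 7.89, 2.74, 9.02, 3.43, 3.45, 8.09, 9.35 and 6.57 in the same clones, and at 7 in the parental sample. DKK4 lay under the background limit in clones 1, 4, 6, 9 and 10, and EGFR in clones 3, 5, 7 and 8. The first component took 64.9% of the variance between SW480 clones (at most 20.3% in shuffled values). Scores were 18.2, -15.2, -18.4, 16.2, -18.4, 14.997, -16.2, -17.5, 15.8, 15.1 and 5.32, and -4.36 for the parental sample. The largest gap between clone scores, 56.2% of their range, parted 5 clones from 6, so the clones' mean lay between both sides.

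The larger distance between SW480 clones was not the result of lower depth alone, since distances from counting noise alone would differ by 0.0190, against 0.241 measured. Noise adds to these distances in squares, so the first value is not a share of the second. It was also not set by scaling, with a lowest value of 0.222 (0.2215) under 4 other scalings, or by 1 clone, with 0.224 (0.2239) as the lowest without a clone. One hypothesis is that the clone states were already mixed in the parental SW480 cells. The residual of the SW480 parental profile from the best mixture of its clones was 0.678 (0.6775), worse than 9 of 11 clones fitted by the others and within their range of 0.441 to 0.933, while the HT-29 parental residual of 0.866 lay above all 11 HT-29 clones (0.354 to 0.738). The test therefore does not exclude the mixture in SW480 and does not show it, and states that arose during culture stay open.

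Genes of chromosome 3 varied together between SW480 clones, with median log2 deviations from each gene's clone median of 0.47, -0.57, -0.25, 0.22, -0.37, 0.23, -0.78, -0.64, 0.33, 0.09 and 0.13 in clones 1 to 11 and -0.54 in the parental sample, where the medians of other genes ran from -0.22 to 0.21 in the clones. Scaling is argued against by a mean pair correlation of at least 0.234 under 4 other scalings. The component shared with other chromosomes is argued against as the whole cause, since the mean pair correlation without it was 0.178, still past the threshold. Each gene is rescaled after its removal, so 0.178 is not a share of the 0.415 measured with it. A single local group of neighbours is argued against as the whole cause by 0.411 between the 19 genes of the first and the 20 of the second part of the gene order, and 0.376 between its first 13 and last 13 genes, where random sets reached at most 0.259 and 0.371 (permutation test, p = 0.0001 in each, the smallest the draws can give). These pairs kept the first component, and chromosome 3 had been picked for its high pair correlation. The parts also moved unequally. In clones 2, 3, 5, 7 and 8 the second part lay at -0.78, -0.575, -0.83, -0.945 and -1.005, and the first at -0.52, -0.07, -0.18, -0.42 and -0.49. Of the other clones, only clone 11 had the larger deviation in the first part. A different copy number of chromosome 3 and regulation shared by these genes cannot be told apart: the clone medians spanned 1.25 log2, but they had the sign of the first component score in all 11 clones, and clones 2, 7 and 8, which passed for chromosome 3 in a test of each clone, no longer did with that component removed, while 8 shifts on other chromosomes passed. No DNA data were analysed here.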
